A study of Halobacterium salinarum NRC-1 with 6 samples.

How the data were processed

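Total RNA of Halobacterium salinarum NRC-1, an archaeon that grows in near-saturated salt, was compared on 2-colour microarrays between cultures given zinc sulfate and a standard control. Per the labels, mid-log cultures were exposed to the metal for 5 h. There were 3 doses (0.005, 0.01 and 0.02 mM), with 1 RNA sample each, and each sample was hybridised against the control on 2 arrays with the dyes Alexa 532 and Alexa 647 exchanged, which gives 6 arrays. The 2 arrays of a dose hold the same RNA pair and counted as 1 replicate. The fits therefore had n = 3 values per feature, 1 per dose. The control RNA was taken as 1 sample, so that its own spread is left out of every test. Nothing in the labels says that the 3 doses came from independently repeated cultures, and p-values measure only the spread between these samples.

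The deposited values are 1 number per spot and array, recorded here as a score, because neither the labels nor the file header states the base of the log, the order of the dyes in the ratio or the steps that led to the values. Scanner, background correction and normalization by the authors are not given in the sources used here. The table has 10752 rows, 6 arrays and no missing value. Column medians were between 0.0878 and 0.175, so the arrays were not centred, and each was centred on its median. Rows fall into 2688 features of 4 rows each, 2 adjacent rows and 2 more exactly 5376 rows further on. This grouping was read from the 133 named genes, all of which follow it, and was extended to the unnamed features. The 4 rows were averaged. The platform annotation, an old one, names 532 rows with 1 gene symbol, none with several, and leaves 10220 rows unnamed, which makes 133 named genes and 2555 unnamed features. All 133 symbols were found in a RefSeq gene table of another strain of the species (91-R6, assembly ASM479960v1), used only for which genes neighbour each other, and no coordinates are given.

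For each dose the turned log ratio is the mean of the array with zinc in Alexa 647 and the array with zinc in Alexa 532 after its sign was changed. A value on the positive side means more RNA in zinc if the deposited ratio is Alexa 647 over Alexa 532, and less RNA in zinc if it is the inverse. Because this is not settled, results are given as positive or negative side, with no statement of induction or repression and no fold.

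The turning departs from the rule fixed before the data were examined. That rule took a positive correlation between the 2 arrays of each dose as a sign that the ratios had already been turned, and the correlations were positive (0.725 to 0.840). They were higher still between arrays of different doses with the same dyes (0.837 to 0.929). The difference between the upper and the lower copy of a feature holds no RNA effect. In the part shared by both arrays of a dose it followed the row order of the table, taken here as position on the array. No array coordinates were used. The mean correlation between features 2 to 24 positions apart was 0.827, against 0.0640 in the part that changes sign with the dye. The shared part was therefore read as dye bias and the ratios were turned. The ratios as deposited were run as an alternative, and their effect is large.

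The mean over the 3 doses was tested against 0, and the slope per doubling of dose against 0, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and Benjamini-Hochberg adjustment over all 2688 features at 0.05. There were 2 residual degrees of freedom for the mean and 1 for the slope before moderation, and moderation added 5.01 and 15.7. The number of arrays limits the precision. Gene lists of at least 4 named genes were tested with camera (preset correlation 0.01), with an estimated correlation, with fry and against 10000 random lists. Of the 21 lists fixed before the data were examined, 6 could be tested, 8 had 1 to 3 named genes and 7 had none. A further 8 lists were written after the gene names were seen and before the values, and were adjusted as a family of their own. For each dose, features at least 2-fold on both arrays were counted under a log10 reading of the values. Plots were drawn with matplotlib 3.10.9.

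Genes to be named were set in advance as up to 12 per side with the largest mean, past the threshold and with the same sign on all 6 arrays, filled by size where fewer passed, and up to 5 slopes per side. The rule was applied among the named genes. Single arrays carry the dye bias, so that 10 of the 20 called named genes miss the same-sign condition. These 10 (gdhA1, htr6, menD, hisI, psmB, purL, tpiA, cobN, ppsA and psmA), the trends of cheR and cca, and the unnamed features singled out were chosen after their values were seen.

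The fits were tested on simulated data with 2688 features. For the mean over 3 doses, 98 of 100 changes of 0.1 and 100 of 100 of 0.2 were recovered, with 16 false calls among 214. For the dose trend the figures were 95 of 100 and 100 of 100, with 25 false calls among 220. Because all doses share the control, unchanged samples against 1 control of equal spread were also simulated 100 times.

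Alternatives were each dye orientation alone, all 6 arrays with a dye term, other centring and scaling, the median of the rows, discordant dye pairs left out, each array or dose left out, other moderation, a fold limit and other list tests. Added after the data were seen were the ratios as deposited, removal of the smooth trend of the turned ratio along the dye bias (loess, span 0.5), each copy of the features alone, the named genes as background of the list test and a log2 reading. The removal was first judged by how many features were called again. For the dose trend that count fell under the bound written for dye bias as the cause. A measure by the share of the effect left was put beside it after that outcome was known, and came out on the other side of its bound. Both are given.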

Results

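Turned log ratios of zinc-exposed against control RNA were obtained for 2688 array features at 3 zinc sulfate doses, 0.005, 0.01 and 0.02 mM, each from 1 RNA sample on 2 dye-swapped arrays. Of the features, 133 carry a gene symbol. Values are in the deposited log-ratio units, whose base is not stated, and the positive side means more RNA in zinc if the ratio is Alexa 647 over Alexa 532 and less if it is the inverse. Errors are the SD over the 3 doses (n = 3) unless another is named.

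The comparison of zinc with control over the 3 doses asked which transcripts differed after exposure to the metal. Among named genes, 11 lay on the positive side past the threshold and 9 on the negative side. The largest positive mean was that of phoU, a regulator of phosphate uptake, at 0.179 ± 0.0654 (adjusted p = 0.0108, positive at 3 of 3 doses). The negative side was led by hemA, which encodes the glutamyl-tRNA reductase that opens haem and cobalamin synthesis, at −0.235 ± 0.149 (adjusted p = 0.0320). It was followed by panB, an enzyme of pantothenate and coenzyme A synthesis, at −0.183 ± 0.0284 (adjusted p = 0.00519), and by serB, phosphoserine phosphatase of serine synthesis, at −0.169 ± 0.0722 (adjusted p = 0.0155), each negative at 3 of 3 doses. The sizes differed between the dye orientations. With zinc in Alexa 647 only and in Alexa 532 only, the means were 0.0499 and 0.309 for phoU, −0.352 and −0.118 for hemA, −0.243 and −0.123 for panB and −0.314 and −0.0244 for serB, and the calls of phoU in the first (adjusted p = 0.194) and serB in the second (adjusted p = 0.191) ended. With the ratios as deposited, not turned, the mean of phoU was −0.129 and those of hemA, panB and serB stayed negative. If the shared part is dye bias, as read here, the means as deposited hold no zinc effect. They bear on these signs only if the ratios had already been turned.

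Among the other called genes on the positive side, the glutamine-dependent glucosamine synthase gene glmS had a mean of 0.108 ± 0.0594 and the glutamate dehydrogenase gene gdhA1 one of 0.105 ± 0.0638. The purine genes purF, for the amidotransferase of the first committed step, and purL had means of 0.0945 ± 0.0278 and 0.0666 ± 0.00962. The means were 0.0677 ± 0.0195 for carB, the large subunit of carbamoyl phosphate synthase, and 0.0705 ± 0.0260 for speB, an agmatinase family gene. The remaining positive calls were rpmC of the large ribosomal subunit (0.0804 ± 0.0147), the transducer gene htr6 (0.0716 ± 0.0239), ppsA for phosphoenolpyruvate synthase (0.0661 ± 0.0183) and the cobaltochelatase gene cobN (0.0631 ± 0.00856). Adjusted p by limma for these 10 genes was between 0.0241 and 0.0481. With the arrays that hold zinc in Alexa 647 used alone, the means of htr6 (−0.0980), purL (−0.0502), cobN (−0.0914) and ppsA (−0.111) were negative, and that of ppsA was −0.00679 without the array with zinc in Alexa 532 at 0.02 mM. Dye bias does not cancel in these settings, so the changes of sign do not measure the zinc ratio alone. The next genes with 1 sign on all 6 arrays, folP of folate synthesis (0.0592 ± 0.0201) and purD (0.0555 ± 0.0155), did not pass.

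On the negative side, both proteasome core genes were called, psmB at −0.136 ± 0.0701 and psmA at −0.0965 ± 0.0319. So were srp19, a protein of the signal recognition particle, at −0.122 ± 0.0796, the histidine synthesis gene hisI at −0.116 ± 0.0593, triosephosphate isomerase tpiA at −0.107 ± 0.0495 and menD of menaquinone synthesis at −0.0787 ± 0.0330. Adjusted p by limma for these 6 was between 0.0246 and 0.0475. With the arrays that hold zinc in Alexa 532 used alone, the means of menD (0.0473), hisI (0.0263), psmB (0.0568) and psmA (0.0573) were positive. The tRNA end-adding enzyme gene cca, at −0.0834 ± 0.0688, did not pass (adjusted p = 0.0900).

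**Figure D1:**
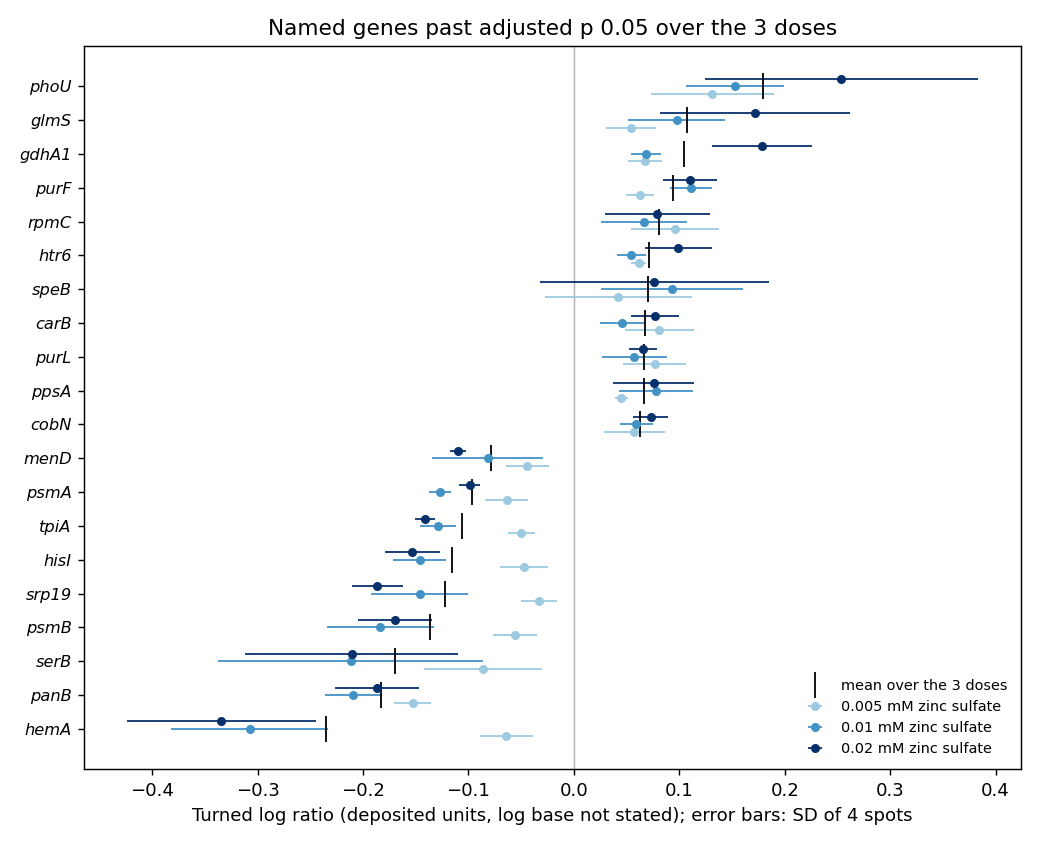
Turned log ratio (horizontal axis, deposited units) of the 20 named genes past adjusted p 0.05 over the 3 doses, 1 point per dose in light to dark blue, with the SD of 4 spots as error bar and a black mark at the mean. Every gene has 1 sign at all 3 doses, which selection by the mean of these values itself favours. The values of hemA run from −0.0641 at 0.005 mM to −0.334 at 0.02 mM.

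Over all features, limma called 222 of 2688, 87 on the positive side and 135 on the negative side, and 750 had an unadjusted p under 0.05. The balance of the sides turned without centring (215 positive, 154 negative) and with quantile normalization (470 positive, 208 negative). Named genes made up 20 of the calls, 15.0% of the 133 against 8.26% of all features. The median absolute mean of the calls was 0.112. The unnamed feature at row_1911 had the mean of the largest size, −0.365 ± 0.112. With any 1 array left out, or without the dose of 0.01 or of 0.02 mM, 0 features passed limma, with 96 to 400 at an unadjusted p under 0.05, and without the dose of 0.005 mM 627 passed. With 1 array left out, the dye bias of that dose does not cancel and adds to the spread between doses. A count of 0 then cannot show whether the calls rest on single arrays. Unchanged samples simulated against 1 shared control of equal spread gave a median of 374 calls (179 to 559), so the count alone does not separate zinc from a deviation of the control, although 170 features exceeded a size of 0.1 against 33 (16 to 49) simulated.

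The dose trend asked whether the turned ratio shifted with the dose of the metal. With all arrays used, all 7 named genes with a trend past the threshold ran toward the negative side. The slope per doubling of dose was −0.135 ± 0.0236 (SE) for hemA (adjusted p = 0.00622). It was −0.0790 ± 0.0183 for guaB, the dehydrogenase at the branch to guanine nucleotides (adjusted p = 0.0317), and −0.0767 ± 0.0187 for srp19 (adjusted p = 0.0337). The enolase gene eno had −0.0749 ± 0.0182 (adjusted p = 0.0337) and msrA, a methionine sulfoxide reductase that repairs oxidised protein, −0.0700 ± 0.0185 (adjusted p = 0.0458). The chemotaxis methyltransferase gene cheR and cca had slopes of −0.0688 and −0.0673, both with an adjusted p of 0.047. These directions did not all hold with a single array left out. The slopes then reached 0.0122 for guaB, 0.0482 for eno, 0.0294 for msrA and 0.0321 for cheR. Those of hemA, srp19 and cca stayed negative. The dye bias of the dose concerned does not cancel in these settings, so the turns do not measure the zinc ratio alone. A slope does not mean a growing distance from control: eno went from 0.0602 at 0.005 mM to −0.0897 at 0.02 mM, msrA from 0.0178 to −0.122 and cheR from 0.00613 to −0.131. The slopes of phoU (0.0612) and glmS (0.0588) did not pass, each with an adjusted p of 0.0745, nor did that of the glycyl-tRNA synthetase gene glyS (0.0537, adjusted p = 0.120).

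In all, limma called a trend in 110 features, 21 positive and 89 negative, with 499 at an unadjusted p under 0.05. By both tests 26 features were called, all with 1 sign, hemA and srp19 among them. The trend calls depended on the processing: 0 remained with equal scale between arrays (331 at an unadjusted p under 0.05) and 3 after removal of the trend along the dye bias (531). With single arrays left out, where the dye bias of that dose does not cancel, the count ran from 0 to 345. Nor does dye bias cancel with only 1 dye orientation used. The balance of the sides turned as well, to 71.7% positive without centring, 82.1% positive with zinc in Alexa 532 only and 80.0% positive without the array with zinc in Alexa 647 at 0.005 mM, which gave the 345.

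Doses were also compared directly. The SD of the turned ratio over all features was 0.0376 at 0.005 mM, 0.0623 at 0.01 mM and 0.0718 at 0.02 mM, while the median spot SD stayed between 0.0256 and 0.0287. The SD of the unturned shared part, read as dye bias, rose as well (0.148, 0.163 and 0.179). The correlation of the turned ratio with it was −0.182, 0.143 and 0.217 at these doses. A growing SD therefore need not be a growing response. Across features, which are not independent replicates, Pearson's r was 0.604 between 0.005 and 0.01 mM, 0.489 between 0.005 and 0.02 mM and 0.817 between 0.01 and 0.02 mM, against 0.501 for simulated unchanged samples sharing a control. The covariances were 1.99, 1.86 and 5.14 times the simulated one. One sign at all 3 doses was seen in 49.3% of features, against 50.1% simulated. The simulation gave every dose the SD at 0.005 mM, below those observed at the higher doses. Its r and its share of 1 sign are therefore not matched to these data. Under a log10 reading, 0, 1 and 2 features were at least 2-fold on both arrays of the 3 doses in ascending order. When the arrays were not turned, which counts the shared part read here as dye bias, the counts were 120, 76 and 135. Under a log2 reading the counts were 0 at each dose. There is 1 RNA sample per dose, so these counts have no replicate test.

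Of the 6 testable lists fixed in advance, chaperones and proteasome was past the threshold. Its 4 genes all had negative means, with a list median of −0.0784, and psmA and psmB were called. The chaperone genes dnaK (−0.0602) and dnaJ (−0.0203) were not called. Adjusted over the list alone, 3 of the 4 passed. Camera gave an adjusted p of 0.0313 for the list. The call ended with an estimated correlation (adjusted p = 0.934) and with all 6 arrays, a dye term and dose as a random block (adjusted p = 0.0518). It also ended without the array with zinc in Alexa 647 at 0.005 mM (adjusted p = 0.483), at 0.01 mM (0.945) or at 0.02 mM (0.886) and without the dose of 0.02 mM (0.0776), and the list passed in 13 of 24 settings. With zinc in Alexa 532 only, its direction turned to the positive side (adjusted p = 0.0610). By camera it was negative as deposited too (adjusted p = 0.0295). The 13 passes include that setting, zinc in Alexa 647 only (0.0195) and each array with zinc in Alexa 532 left out (0.00230, 0.00867 and 0.0123). In these settings, and without an array with zinc in Alexa 647, dye bias does not cancel, so they do not bear on zinc alone.

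The other lists did not pass camera. In cobalamin and haem synthesis, cobN was called on the positive side and hemA on the negative side among 6 genes, 5 passed when adjusted over the list alone, and the list median of 0.0323 and mean of −0.0170 differ in sign. None of the 12 aminoacyl-tRNA synthetase genes was called, with means from −0.0338 to 0.0501, and none passed when adjusted over the list alone. Among 11 flagella and chemotaxis genes htr6 was called, and it was the 1 gene to pass when adjusted over the list alone. In the citric acid cycle (6 genes) and the bacteriorhodopsin list (4 genes), 0 genes were called over all features and 1 gene each when adjusted over the list alone. Adjusted p by camera for these 5 lists was between 0.769 and 0.863. No gene of the metal efflux list or of the zinc and manganese uptake list is among the 133 named genes, so these groups were not analysed here. In the oxidative stress list the 1 named gene was msrA, with a mean of −0.0629 ± 0.0724 (adjusted p = 0.179).

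**Figure D2:**
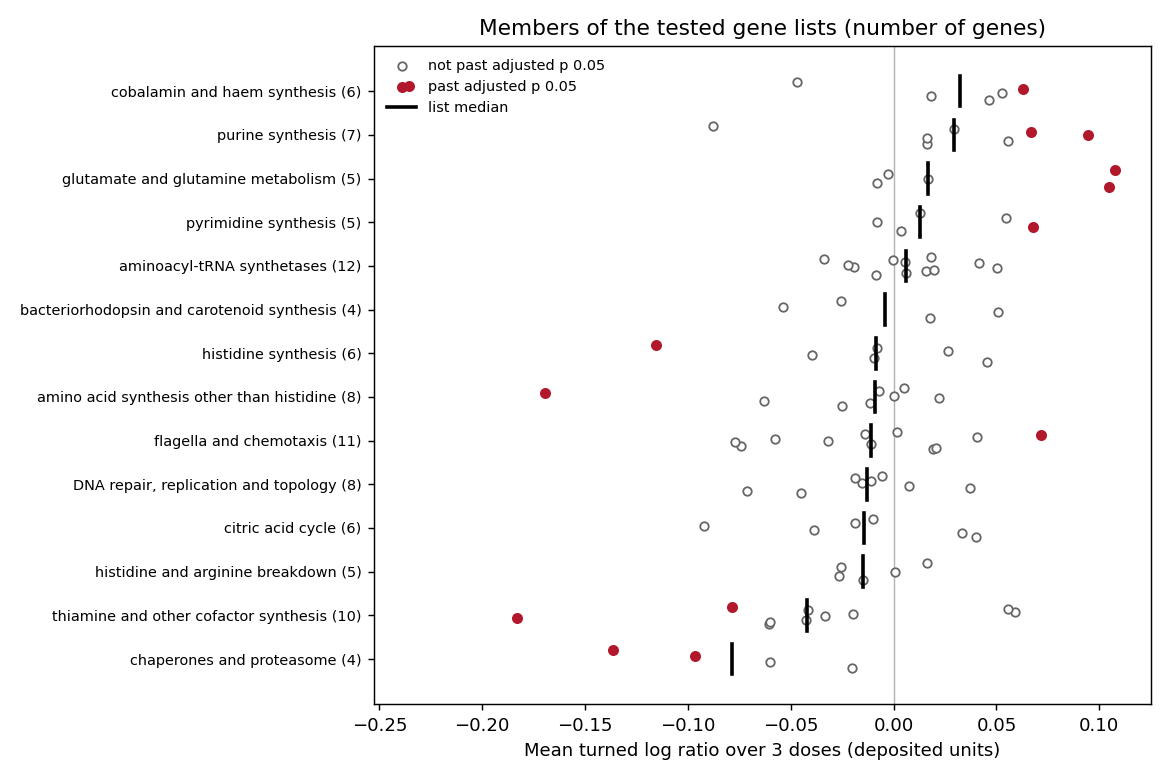
Mean turned log ratio over the 3 doses (horizontal axis, deposited units) of each member of the 14 tested lists, with filled points for genes past adjusted p 0.05 and a bar at the list median. The chaperone and proteasome list has the lowest median, −0.0784.

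**Figure D3:**
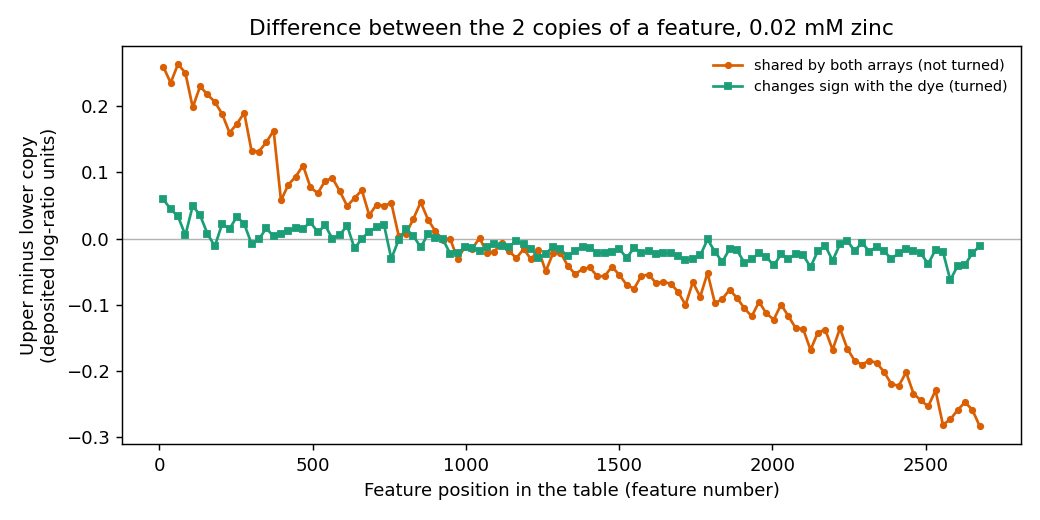
Upper minus lower copy of each feature at 0.02 mM (vertical axis, deposited log-ratio units) against position in the table, averaged in bins of 24 features, for the part shared by both arrays and the part that changes sign with the dye. The shared part slopes along the table, and the turned part does so less steeply, from 0.0593 in the first bin to −0.0627 at position 2580.5. The mean neighbour correlation over the 3 doses was 0.827 in the shared part against 0.0640 in the turned part. At 0.02 mM alone it was 0.833 against 0.110.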

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

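Of the tests here, those of the dye bias left after averaging and of the dose orders were chosen after the result was seen. The measure by the share of the effect left was added once the count of features called again was known.

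A difference between doses marks 110 features whose slope per doubling of dose passed limma's adjusted p of 0.05. Named among them are hemA (−0.135), guaB (−0.0790), srp19 (−0.0767), eno (−0.0749), msrA (−0.0700), cheR (−0.0688) and cca (−0.0673).

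After the smooth trend along the dye bias was removed, 3 of the 110 features were called again, under the bound written for dye bias as the cause. The slopes themselves argue against that smooth trend as the whole cause: a median of 82.7% of the slope was left (quartiles 73.5% and 95.8%), and all 110 kept their sign and an unadjusted p under 0.05. The correlation of the turned ratio with the dye bias was −0.182, 0.143 and 0.217 in ascending order of dose. The smooth trend thus held little of the ratio, and its removal could hardly take most of a large slope away. Dye bias off the smooth trend was not tested. The median absolute slope went from 0.0794 (median SE 0.0186) to 0.0697 (0.0156), and the degrees of freedom added by moderation fell from 15.7 to 6.02. How much each change counted for the lost calls was not tested. For hemA the slope went from −0.135 ± 0.0236 to −0.120 ± 0.0252 (SE), for srp19 from −0.0767 ± 0.0187 to −0.0768 ± 0.0148, and for eno from −0.0749 ± 0.0182 to −0.0457 ± 0.0168. A partial contribution of dye bias and a response to zinc dose stay open. Of the 3 orders of the doses, 1 gave as many calls, the real order with 110 against at most 17, and 3 orders are too few for a share under 0.05.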

How the results depend on the processing

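The ratios as deposited, the removed dye-bias trend, the upper or lower copies alone, the named-gene background and the log2 reading were chosen after seeing the data. Where no cause is given, the cause was not tested.

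The 222 calls over 3 doses (39.2% positive) became 1924 with zinc in Alexa 647 only and 2157 in Alexa 532 only, where the dye bias does not cancel, and 2184 as deposited. They became 367 with 6 arrays and a dye term, 369 without centring (58.3% positive), 678 with quantile normalization (69.3% positive), 139 without discordant dye pairs (1302 features tested), 34 with a 1.5-fold limit and 0 in the unmoderated test (373 at an unadjusted p under 0.05). Leaving out an array or dose gave 0 to 627. With 1 array left out the dye bias of that dose does not cancel, and with 1 orientation used that of every dose does not. Both limits hold for the trends and lists below too. Equal scale, row medians, trend and robust moderation, dye-bias removal and the upper or lower copies alone gave 165 to 318.

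The 110 trend calls (19.1% positive) became 274 with Alexa 647 only, 67 with Alexa 532 only (82.1% positive), 290 without centring (71.7% positive), 68 with row medians, 31 with the lower copies and 3 after dye-bias removal. They became 0 with equal scale (331 at an unadjusted p under 0.05), quantile normalization (418), the upper copies (330), the unmoderated test (209), as deposited (565) and with a 1.5-fold limit. Leaving out an array gave 0 to 345. Slopes with a dose left out have no residual degrees of freedom.

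The 1 list past the threshold became 4 with Alexa 647 only, all negative, 3 with Alexa 532 only, all positive and without chaperones and proteasome, 5 as deposited, all negative, and 0 with the dye term, equal scale, the lower copies, an estimated correlation, fry and random lists. With discordant pairs left out this list had too few genes to be tested. Leaving out an array or dose gave 0 to 3. The 2-fold counts of 0, 1 and 2 features became 1, 9 and 13 at 1.5-fold. They were 9 and 9 at 0.01 and 0.02 mM by the mean of the arrays, 0 and 1 with quantile normalization and 0 and 0 read as log2.

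As deposited, the means of phoU (−0.129), glmS (−0.0222), purF (−0.00335), rpmC (−0.0267), speB (−0.00488), carB (−0.0456), gdhA1 (−0.0973), htr6 (−0.170), purL (−0.117), cobN (−0.154) and ppsA (−0.177) changed sign. With Alexa 647 only, htr6 (−0.0980), purL (−0.0502), cobN (−0.0914) and ppsA (−0.111) did, and with Alexa 532 only menD (0.0473), hisI (0.0263), psmB (0.0568) and psmA (0.0573). Within 1 orientation dye bias does not cancel, so the changes of sign by orientation do not measure the zinc ratio alone. The called negative means stayed negative as deposited. If the shared part is dye bias, the means as deposited hold no zinc effect and cannot weigh on these signs. With arrays or doses left out, 12 of the 20 called means and all 7 called slopes moved by over 1.5 times. With 1 array left out the dye bias of that dose does not cancel, so such moves hold dye bias and do not measure the zinc ratio alone. The slope of hemA ran from −0.243 to −0.0268, that of srp19 from −0.113 to −0.0400 and that of cca from −0.0924 to −0.0421. The means of ppsA ran from −0.00679 to 0.139, cobN from 0.00436 to 0.122, htr6 from 0.0135 to 0.130, purL from 0.0212 to 0.112, gdhA1 from 0.0672 to 0.142, carB from 0.0433 to 0.0921, menD from −0.135 to −0.0223, psmA from −0.165 to −0.0278, psmB from −0.215 to −0.0579, hisI from −0.172 to −0.0597, tpiA from −0.154 to −0.0593 and serB from −0.230 to −0.109, and the slopes of guaB from −0.170 to 0.0122, eno from −0.198 to 0.0482, msrA from −0.169 to 0.0294 and cheR from −0.170 to 0.0321.

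Requiring a value on all 6 arrays changes nothing, as none is missing. The dye pair of a dose was blocked in the fit of 6 arrays with a dye term (367 and 145 calls). Replicate numbers, given in accession order, paired nothing across doses. Signal over background is not given in the sources used here.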

Other observations

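Of the tests here, those of the dye bias left after averaging, the control RNA, the sign patterns and the neighbouring genes were chosen after the result was seen.

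Among the lists written after the gene names were seen, purine synthesis had 6 of 7 means on the positive side, with purF and purL called and guaB at −0.0880, which did not pass (adjusted p = 0.102). The adjusted p by limma's camera was 0.118, so the list did not pass. It passed in 2 of 25 settings, by fry (adjusted p = 0.0173) and with discordant dye pairs left out (adjusted p = 0.0172), and the highest adjusted p was 0.807. In thiamine and other cofactor synthesis 8 of 10 means were on the negative side, with panB and menD called, and the adjusted p by camera was 0.160. The glutamate and glutamine list held the calls of gdhA1 and glmS (adjusted p = 0.167), pyrimidine synthesis that of carB (0.167), histidine synthesis that of hisI (0.767) and other amino acid synthesis that of serB (0.417). Histidine and arginine breakdown (0.767) and DNA repair, replication and topology (0.580) held none.

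Of the lists too small to test, phosphate transport held phoU, which was called, and oxidative stress held msrA, whose slope was called. In the others, means were −0.0595 for the iron storage gene dpsA, 0.0371 for mutL, −0.0448 for uvrA, −0.0710 for uvrB, 0.0437 for rpl12p, 0.00981 for nuoL, −0.0921 for sdhC, −0.0258 for arcA, 0.0161 for arcC and 0.0483 for csg. None of these last 10 genes was called.

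The unnamed feature at row_4245 had a mean of 0.195 ± 0.00187 (SD, n = 3 doses), nearly the same value at each dose, with an adjusted p of 0.00376 by limma. That at row_4433 ran from 0.146 at 0.005 mM to 0.394 at 0.02 mM.

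The part of the ratio shared by both arrays of a dose may be dye bias that follows the array position, which was read from the row order of the table. The difference between upper and lower copies had a mean neighbour correlation of 0.827 there, above the bound set in advance. Had the ratios been deposited already turned, that correlation would be larger in the part that changes sign with the dye, where it was 0.0640. The shared part also agreed between the upper and lower copies of a feature, with r of 0.725 to 0.755. The neighbour correlation of the upper copies was 0.273 to 0.304, so position alone does not account for the shared part. The position pattern argues against a zinc response as its source.

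Of the 222 features called over the 3 doses, 220 were called again after the smooth trend along the dye bias was removed, with a median of 95.3% of the mean left. The correlation of the turned ratio with the dye bias was −0.182, 0.143 and 0.217 in ascending order of dose. The smooth trend thus held little of the ratio, and its removal could hardly have changed most means. Both measures argue only against that smooth trend as the whole cause. Dye bias off the smooth trend was not tested. A deviation of the single control RNA could give the same value at each dose, as unchanged samples against 1 control of equal spread correlate by 0.501 between doses. The share of features with 1 sign at all doses (49.3% against 50.1%) and r between 0.005 and 0.02 mM (0.489) do not exceed that simulation. This decides nothing, because every simulated dose had the SD at 0.005 mM (0.0376), against 0.0623 and 0.0718 observed at the higher doses. A larger SD of the samples lowers the r and the share of 1 sign that a shared control alone gives. Other values exceed the simulation, with r of 0.604 and 0.817 for the other pairs of doses and covariances of 1.86 to 5.14 times the simulated one. That simulation gave control and samples equal shares of the variance at 0.005 mM. For covariances of 1.86 and 1.99 times, the control would have to hold nearly all of that variance. The turned values of the upper and lower copies correlated by only 0.553 at 0.005 mM, so part of that variance is measurement spread. This argues against the control alone as the source of these covariances. In a second simulation, with the residual spread of each feature, at most 49 features exceeded 0.1 and 10 exceeded 0.15, against 170 and 58 observed. Such a deviation of the control is constant over the doses, so it does not account for the difference of hemA between −0.0641 and −0.334. For single features with values alike at each dose, a control of larger spread cannot be told apart from zinc. Of the 4 sign patterns of the doses, 1 gave as many calls, the real one with 222 against at most 0, and 4 patterns are too few for a share under 0.05. A control shared by all doses also favours the real pattern, so this contrast does not separate zinc from the control. A zinc response remains a hypothesis.

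Neighbouring genes may share transcription. In 24 pairs with at most 1 gene between them in the related strain the one-sided permutation p for closer means was 0.0684, which leaves this open.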
